A study of Mus musculus with 2 samples.

How the data were processed

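Total RNA of purified CD4+ T cells was converted to biotinylated cRNA and hybridised to the 2 chips of the Affymetrix Mu11k set, per the labels. The 2 samples are 1 array per chip, both labelled Ac1-11, and there was no replicate. The levels are deposited as array intensity values per probe set, in average difference units (perfect match minus mismatch), with 20.8% of them below 0 on subA and 35.5% on subB. Per the file headers, the authors' fold and ratio values have the column names of Affymetrix 2-array comparison output, and the software's version, noise settings and scaling are not stated there or in the labels. They give for each probe set an average difference, its change from a baseline array, a signed fold, a presence call, a difference call and the number of probe pairs scored as increased or decreased. The series' design text describes the results as ratios of mean average differences, 4Y over Ac1-11. The levels deposited for each sample and those of the experiment array in the comparison table were compared value by value and were identical for 6584 and 6595 probe sets. As sample label and experiment name then disagree, results are given as deposited over baseline array.

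The deposited fold was used as it stands and turned into a signed log2 fold. Folds marked as approximate (2330 on subA, 4106 on subB) were kept, are called approximate in the text and were left out of rankings. They come close to 1 plus the size of the change divided by a noise value of about 90.7 on subA and 414 on subB, so they can lie far above or below the ratio of the levels. The level of the baseline array was computed as the deposited level minus the deposited change. From it, 94.9% of exact folds of detected probe sets on subA and 93.5% on subB could be recomputed within 0.15 on the log2 scale, so a fold printed beside levels can differ from their ratio. A baseline marked with an asterisk was read as absent, because the median implied baseline level was 58 on subA and 62 on subB where it stands, against 1253 and 2708 elsewhere.

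Probe sets were named through the platform annotation, with symbols looked up by Entrez ID in RefSeq genes of GRCm38.p6, which altered 0 symbols. On subA 5560 probe sets had 1 gene symbol, 197 several and 827 none. On subB the numbers were 2001, 27 and 4567, and unnamed probe sets are given by their ID. A probe set counted as changed with a deposited fold of at least 2 either way, a difference call of increase or decrease (marginal calls counted with neither side) and a presence call in at least 1 condition, where a baseline not marked absent counts as present. The 55 control probe sets of each chip were left out. This is a rule of size, not a test, and it admits genes whose lower level was called absent, for which the size of the fold is uncertain.

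A total of 35 gene lists were fixed before the data were examined, as were the rules for changed and named genes and the first set of alternatives. Each list's median log2 fold over detected genes used the probe set with the highest mean of deposited and implied baseline level per gene and chip. It is given with its percentile among 10000 random lists of the same size, matched in 10 bins of level. With both chips joined, a gene detected on both enters once for each chip, so its values can cancel. Lists with fewer than 4 detected genes have no percentile. The percentile describes these arrays only. The text names the 12 largest exact increases and decreases, changed members and up to 4 unchanged members with a high level of the immune lists, up to 4 changed members of other lists, and a fixed set of cytokine, receptor and lineage genes such as Ifng, Il4 and Cd4 whatever their value. Columns of other samples numbered 0. Correlations between chips, chosen after the data were seen, used genes detected on both.

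Alternatives were other fold thresholds, calls and detection filters, median centring per chip, folds recomputed with floors, each chip alone and the median over probe sets. Alternatives added after the data were seen were removal of a running median over 300 probe sets ordered by level, turning the sign of subB, taking the probe set with the highest deposited level, leaving out approximate folds and subsets of genes for the correlation. The procedures were tested on simulated data. With lists of 10 genes shifted by 1 on the log2 scale, 20 of 20 were placed above the central 95% of random lists, with a shift of 0.5 15 of 20, and with no shift 0 of 20. Of 200 simulated changes of 1.6 on the log2 scale on subA, 193 were counted, with 5 unchanged probe sets. Difference calls there were set from the simulated fold and every probe set was taken as detected, so only the fold threshold was tried. The simulated noise was also smaller than the spread between probe sets of the same gene on subA. Work was done in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.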

Results

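The study profiled CD4+ T cells purified from spleen and lymph node of B10.PL mice that carry a transgenic T-cell receptor for Ac1-11, the acetylated N-terminal peptide of myelin basic protein. The labels give a time of 48 h. RNA was read on the Affymetrix Mu11k pair of chips, called subA and subB, which hold 6584 and 6595 probe sets. The question set by the series is how expression after stimulation with 4Y, a stimulus that the labels name without describing it, differed from that after Ac1-11. For each chip there was 1 array with deposited levels and 1 comparison of that array with a baseline array. No condition had a replicate array in the deposited data, so no p-value is given, and the number of arrays limits the precision of every value. Folds, difference calls and probe pair counts below are values of the authors' deposited table for each chip. Between 2 probe sets of the same gene, the deposited log2 folds had a per-probe-set SD of 0.45 on subA (285 genes) and 0.63 on subB (51 genes).

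The direction of the comparison was not settled by the files. The levels deposited under the sample label Ac1-11 were identical, for 6584 of 6584 probe sets on subA and 6595 of 6595 on subB, to those of the experiment that the authors' deposited table names 4Y. In addition, the folds of the 2 chips ran in opposite directions for the same genes, as described further on. The array with deposited levels is therefore called the deposited array, the other the baseline array, and each chip is described by itself, always as deposited over baseline. The deposited array had 2967 probe sets called present on subA (45.1%) and 1463 on subB (22.2%). On the baseline array, 3007 and 1467 probe sets were not marked absent.

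On subA, the cytokine genes Ifng, Il4 and Csf2, 3 of 5 chemokine genes and 4 of 5 cytotoxic granule genes counted as lower on the deposited array, and 3 of 14 interferon-induced genes counted as higher. In the authors' deposited table for subA, Ifng, the cytokine interferon-gamma, was 102-fold lower, with 17 of 20 probe pairs scored as decreased. Il4, the defining cytokine of Th2 cells, was 39.9-fold lower by 1 probe set and 31.4-fold lower by the other. The chemokine Ccl1 was 129.7-fold lower, and Csf2, which encodes GM-CSF, was 24.8-fold lower. The deposited levels of Ifng, Ccl1 and Csf2, at 105, 138 and 251 average difference units, were called absent, as was that of the first Il4 probe set, so the size of these folds is uncertain. The same holds for the folds of Gzmd, Gzmc, Crabp2, Tnfsf11 and Cdkn2a given below. The largest increase with an exact fold was that of Man2b1, a lysosomal mannosidase, at 14.7-fold, followed by the interferon-induced antiviral gene Mx1 at 11.8-fold. Ido1, an interferon-induced tryptophan-degrading enzyme that is named here because its value was seen, was higher by an approximate 74.4-fold. The baselines of Mx1 and Ido1 were marked absent. In all, 149 of 3343 detected probe sets counted as changed at least 2-fold, 59 higher and 90 lower.

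Among the Th1-associated genes detected on subA, Ifng and Csf2 were the 2 of 7 that counted as changed. The list's median log2 fold was -0.14, inside the random range (percentile 22.1). Irf1, Il12rb1, Stat4 and Ltb had folds of 1.3 higher, 1.1 lower, 1.2 higher and 1.4 lower in the authors' deposited table. Among the 9 Th2-associated genes, 3 counted as lower and 1 as higher, with a median of 0.14, inside the random range (percentile 71.0). These were Il4, Il13 (2.3-fold lower, 15 of 20 probe pairs), Il10 (2.7-fold and 2.6-fold lower by its 2 probe sets) and the transcription factor gene Epas1 (2.0-fold higher by 1 probe set, 1.2 by the other). Il4ra and Nfil3 were 1.4-fold and 1.6-fold higher and did not count. Of the 5 chemokine genes detected, 3 counted as lower: Ccl1, Ccl9 (9.2-fold, 20 of 20 probe pairs) and Ccl4 (7.1-fold, 18 of 20). The other Ccl4 probe set, MIP1-B_at, was 2.6-fold lower with no difference call, with 13 of 20 probe pairs decreased and 5 increased. Ccl5 (1.6-fold lower) and Ccl2 (an approximate 2.8-fold higher) had no difference call. The list's median log2 fold was -2.83, at percentile 0 of 10000 random lists matched on level, and -1.38 (percentile 0.015) with the probe set of the highest deposited level for each gene. Of 5 cytotoxic granule genes, 4 counted as lower: Gzmd (12-fold), Gzmc (an approximate 9.7-fold), Serpinb9, an inhibitor of granzyme B (4.5-fold), and Gzmb (2.1-fold). Lamp1 was 1.3-fold higher, and the list's median was -2.17, at percentile 0.

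Fasl, the ligand of the death receptor Fas, was 2.5-fold lower in the authors' deposited table and was the 1 of 10 apoptosis-promoting genes that counted as changed, while Casp4 and Daxx were each 1.2-fold lower. Fas itself had folds of 1.3 lower and an approximate 2.6 higher by its 2 probe sets, neither with a difference call. Of 6 activation markers, only Tnfsf11, the cytokine RANKL, counted as changed, with an approximate fold of 2.9 lower. Il2ra, Tnfrsf18 and Bsg had folds of 1.2 lower, 1.2 higher and 1.1 higher. Tnfrsf9 and Cd28, named because their values were seen, had decrease calls with folds of 1.3 and 1.6 lower. The median log2 fold of the activation markers was -0.32, inside the random range (percentile 4.39). The phosphatase gene Ptpn6 (2.8-fold lower) was the 1 of 8 negative regulators that counted, while Socs1, Cish and Ptpn22 had folds of 1.2 lower, 1.0 higher and 1.6 lower. Nrp1 (3.4-fold lower) and Il10 were the 2 of 5 regulatory T cell markers that counted. Ccr7, a receptor for lymph node homing, was 2.3-fold lower, the 1 of 6 resting T cell genes that counted, with Satb1 and Btg2 at 1.1 and 1.7 higher, and the gut-homing integrin gene Itgb7 was 3.4-fold higher. No member of the survival list (10 detected) or of the immediate early list (7 detected) counted as changed. Traf1 had a fold of 1.2 lower and Junb of 1.1 lower.

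Interferon-induced genes were the list with the highest percentile on subA. Of 14 detected members, 12 had a fold above 1 and 3 counted as changed, all higher: Mx1, Iigp1 (4.9-fold) and Irf9 (2.4-fold). The baseline of all 3 was marked absent, so their folds are over a signal not told from background. The list's median log2 fold was 0.63, at percentile 100 of the random lists. On subB the 3 detected members were lower without a difference call: Ifi47 (an approximate 1.9-fold), Psmb8 (1.3-fold) and Psmb9 (1.6-fold), of which Psmb8 and Psmb9 were 1.2-fold and 1.6-fold higher on subA. Several lists lay below the random range on subA. The G2/M list had a median of -0.49 (percentile 0.635), with 11 of 15 genes below 1. The G1/S list had a median of -0.26 (percentile 1.55), with 18 of 22 genes below 1 and Mcm6 3.3-fold lower by 1 of its 2 probe sets. The 4 sterol biosynthesis genes had a median of -0.92 (percentile 0.12), with Idi1 2.2-fold lower, and the 26 proteasome genes one of -0.26 (percentile 0.345), with Psmd8 2.0-fold lower. The list of CDK inhibitors and tumour suppressors lay above it on subA, with a median of 0.58 (percentile 99.9). With both chips joined its median was 0 as deposited and 0.58 (percentile 99.9) with the sign of subB turned. Its member Rbl2, of the retinoblastoma family, was 2.1-fold higher, while Cdkn2a was lower by an approximate 14.3-fold.

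Ribosomal protein genes were also higher on the deposited subA array, 22 of 24 with a fold above 1 and none counted as changed, with a median log2 fold of 0.43 (percentile 99.9). Probe sets in the top 5% of levels had a median log2 fold of 0.38 on this chip, against 0 for the rest. The 6 bacterial spike-in probe sets called present were 1.5- to 2.1-fold higher, and so were the Gapdh control probe sets (1.5- to 1.6-fold) and the Actb control probe sets (1.6- to 1.9-fold). The 3 other Actb probe sets on the chip had folds between 1.0 and 1.9 lower. With the running median over the level removed, the ribosomal protein list's median was 0.11 (percentile 93.1), and that of the interferon-induced genes was 0.56 (percentile 100).

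On subB, 4 of 6 Th2-associated genes and 4 of 6 negative regulators of T-cell activation counted as higher on the deposited array. In the authors' deposited table for subB, Il5, a Th2 cytokine that acts on eosinophils, was 8.1-fold higher, with 18 of 20 probe pairs scored as increased and a level of 83175. The chemokine gene Ccl3 was higher by an approximate 165-fold, with 20 of 20 probe pairs increased. Its level was 71307 and the implied baseline level 3421, a far smaller ratio. Inhba, which encodes an activin subunit, was 6.1-fold higher, Ccl1 5.8-fold and Rgs16, a regulator of G-protein signalling, 5.6-fold. The baselines of Ccl1, Ccl3 and Rgs16 were marked absent, so the size of their folds is uncertain, and the same holds for the approximate folds of Il3, Il6, Il9, Csf2, Egr2, Tnfaip3, Tfrc and Serpinb9 on this chip. Itgb2, the beta chain of LFA-1, was 3.7-fold lower, and Gzma, granzyme A, was 3.5-fold lower with 18 of 20 probe pairs decreased. In all, 113 of 1813 detected probe sets counted as changed, 77 higher and 36 lower. Of these, 63 could be named.

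Of 6 Th2-associated genes detected on subB, 4 counted as changed, all higher: Il5, Il9 (an approximate 7.2-fold), Il3 (an approximate 6.9-fold) and Il6 (an approximate 3.0-fold). Gata3, the transcription factor of Th2 cells, and Maf were 1.4-fold and 1.8-fold lower and did not count. The list's median log2 fold was 2.19, at percentile 100 of the random lists. Csf2, the only Th1-associated gene detected under its name, was higher by an approximate 8.4-fold. The chemokine genes detected under their names, Ccl3 and Ccl1, were higher, as was MIP1-B_at (9.8-fold), which the annotation of subA names Ccl4. Of 6 negative regulators of T-cell activation, 5 had a fold above 1 in the authors' deposited table and 4 counted as changed at least 2-fold. The 4 were Ctla4, an inhibitory receptor (3.4-fold, 14 of 20 probe pairs), Lag3, another (2.2-fold), and Egr2 and Tnfaip3 (approximate folds of 2.9 and 2.6). The list's median was 1.26, at percentile 100. Nfkbia had an increase call at 1.9-fold by each of 2 probe sets, and Pdcd1 was 1.3-fold lower.

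The survival genes Cflar, which blocks caspase-8 activation, and Gadd45b were 3.2-fold and 2.3-fold higher in the authors' deposited table for subB, 2 of 7 detected, while Pim1, Akt1 and Pim2 had folds of 1.1 higher, 1.1 lower and 2.7 lower without a difference call. The transferrin receptor gene Tfrc (an approximate 3.0-fold higher) was the 1 of 6 activation markers that counted, and Tnfrsf4 and Cd53 had folds of 1.5 lower and 1.1 higher. Ctla4 and Lag3 were the 2 of 6 regulatory T cell markers that counted, with Capg at 1.2 lower, and Egr2 was the 1 of 6 immediate early genes. Jund had folds of 1.6 and 1.2 lower, and Ier3 of 1.3 higher. Serpinb9 was higher by an approximate 10.6-fold and Gzma lower, the 2 of 5 cytotoxic granule genes that counted, with Srgn at 1.1 lower and Ctla2a at 1.6 lower. Neither of the 2 apoptosis-promoting genes (Cycs and Bak1) nor of the 2 resting T cell genes (Btg1 and Il6st) counted. Within the T-cell receptor complex, Cd3g was 2.1-fold lower and Zap70, the receptor's kinase, 2.0-fold higher. Cd4 had a decrease call with a fold of 1.4 lower. The MYC-responsive growth genes had a median of 0.49 (percentile 98.8), with Ncl, nucleolin, 2.1-fold higher. The remaining named decreases with an exact fold included Tle5 (7.7-fold), Ccng1 (3.0-fold), Ndufa1 (2.6-fold) and Il1r2 (2.6-fold).

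**Figure D1:**
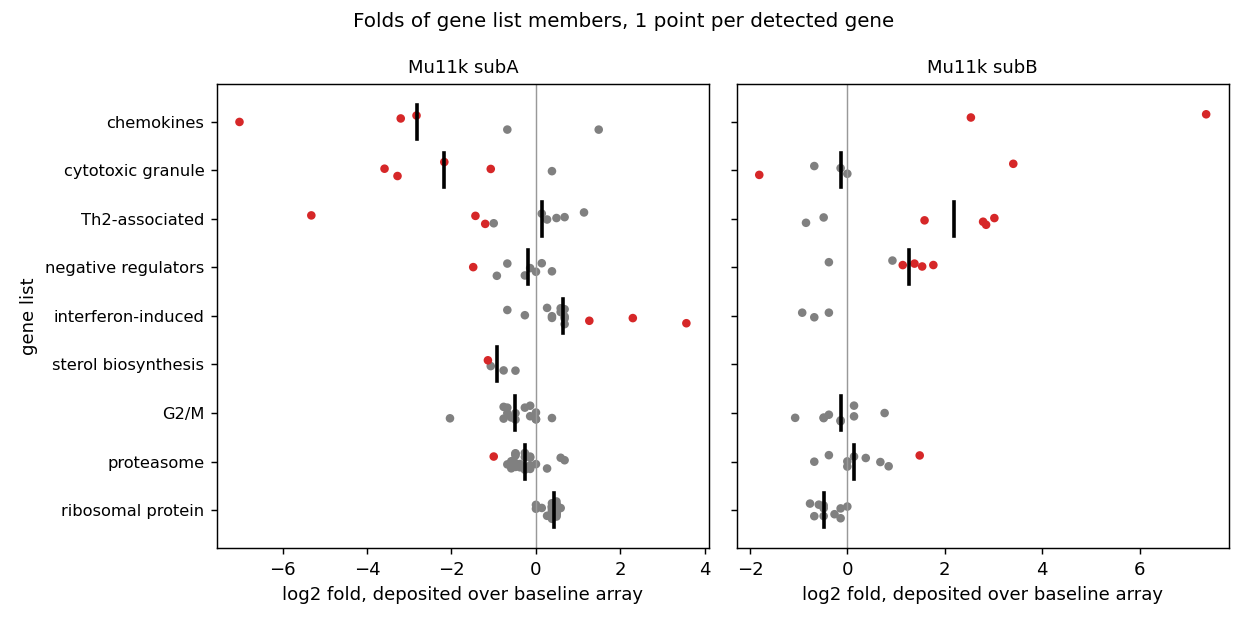
Log2 fold of the deposited over the baseline array for each detected gene of 9 gene lists on subA (left) and subB (right), from the probe set with the highest mean level of the 2 arrays. Red points counted as changed, grey points did not, and black bars are medians of at least 4 genes, such as -2.83 for chemokines on subA and 2.19 for Th2-associated genes on subB.

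The 2 chips could be set against each other through 135 named genes detected on both. Across these genes, which are not independent replicates, the log2 folds had a Spearman correlation of -0.41 and a Pearson correlation of -0.56. Signs were opposite for 72 genes and equal for 40, and 23 had a fold of 1.0 on a chip. Shuffling the genes 2000 times put 95% of the rank correlations between -0.17 and 0.17. Within a chip, 2 probe sets of the same gene had a rank correlation of 0.54 on subA and 0.63 on subB. The authors' deposited table calls 10 genes increased or decreased on both chips, a set found after the values were seen, and all 10 had opposite directions: Il4, Il10, Csf2, Ccl1, Ccl4, Rgs16, Serpinb9, Hspa5, Gsn and Psmd8. Il4, Il10 and Csf2 were each called by the same probe set on both chips (IL4_at, IL10_at and GMCSF_at), in opposite directions. For Il4 and Il10, the subA value used here comes from another called probe set with a higher mean level. The Ccl4 probe set called on subB had no difference call on subA. For Il4, Il10, Csf2 and Ccl4, the subB value came from a probe set that has a gene name only in the annotation of subA.

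**Figure D2:**
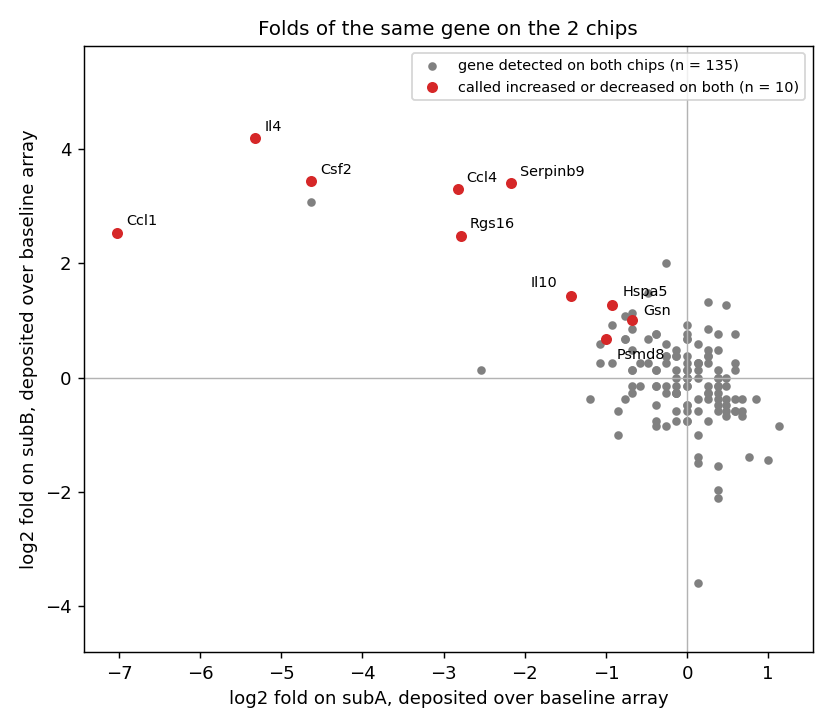
Log2 fold of the deposited over the baseline array on subB against that on subA, 1 grey point for each of 135 named genes detected on both chips. Red points are the 10 genes that the authors' difference call scores on both chips, each from its called probe set with the highest mean level, and all 10 lie below 0 on subA and above 0 on subB.

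Both chips carry 76 probe sets in common, 55 of them controls, which allowed the same comparison on identical probes. Those given here were not taken by a fixed rule, and the other shared probe sets that are not controls are not tallied. IL4_at had a level of 240 on the deposited subA array and 7451 on the deposited subB array, and the baseline levels implied by the authors' deposited table were 7550 and 310. GMCSF_at had levels of 251 and 6216, with implied baseline levels of 6226 and -858, and IL10_at had levels of 1622 and 5020, with implied baseline levels of 4253 and 1646. MIP1-B_at had levels of 5163 and 70759 and implied baseline levels of 13654 and 10662, with an increase call on subB (9.8-fold) and none on subA (2.6-fold lower). TCRa_at, whose ID points to the T-cell receptor alpha chain although the annotation of subA names it Atf2, was 1.6-fold higher on subA and 1.2-fold lower on subB, and had no difference call on either chip. On subB the 5 spike-in probe sets called present had a median log2 fold of 0, and the top 5% of levels one of -0.26.

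**Figure D3:**
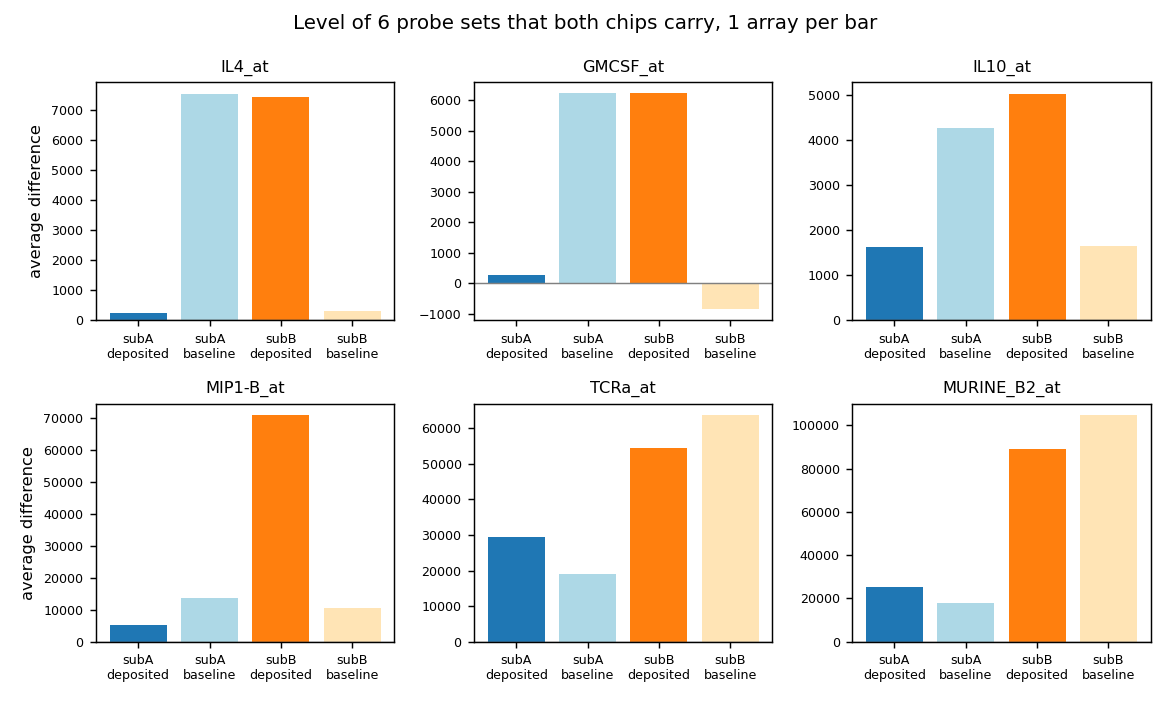
Level in average difference units of 6 probe sets carried by both chips, on the deposited array and as implied for the baseline array, with 1 array per bar and no replicate. IL4_at reads 240 and 7550 on subA but 7451 and 310 on subB, while TCRa_at reads 29540 and 18943 on subA and 54539 and 63635 on subB.

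Taken as deposited, both chips together held 262 changed probe sets, 136 higher and 126 lower. With the sign of subB turned, 95 were higher and 167 lower. Of the 12 named genes with the largest exact increases, 7 came from subA and 5 from subB as deposited, and 9 and 3 (Tle5, Itgb2 and Gzma) with the sign of subB turned. Those not yet given were Ctsh (5.4-fold) and Crip2 (4.2-fold), then Prc1 (3.9-fold) and Fyb (3.8-fold), all on subA, and Snhg6 (4.2-fold) on subB. The baselines of Ctsh and Prc1 were marked absent. Of the 12 named genes with the largest exact decreases, 11 came from subA either way, and the 1 from subB was Tle5 as deposited and Il5 with the sign turned. Among them were Sema7a (11.3-fold), Crabp2 (11.0-fold), Olr1 (10.6-fold), Nfkbiz (8.5-fold) and Gem (7.3-fold). Probe sets without a gene name on their chip are not in this ranking, among them 5 on subB that were 9.7- to 10.8-fold higher, such as GMCSF_at (10.8-fold over an absent baseline) and x51834_f_at (10.6-fold), and J04179_f_at (14.5-fold lower on subA, with an absent call). With both chips joined, a gene detected on both entering once for each, 8 of 31 lists had a median outside the central 95% of random lists. The chemokines (-0.68, percentile 0.45), cytotoxic granule genes (-0.87, percentile 0) and dendritic cell markers (-0.79, percentile 0.24) were among the 6 below, and interferon-induced (0.58, percentile 100) and ribosomal protein genes (0.38, percentile 99.8) were the 2 above. Alternative analyses of both chips put the chemokine, sterol biosynthesis and ribosomal protein lists inside the range and the Th2-associated, G2/M and B-cell lists outside it. With the sign of subB turned there were 15 such lists, now with the Th2-associated genes at -1.0 (percentile 0) and the negative regulators at -0.80 (percentile 0), against 0.26 and 0.07 as deposited. The chemokines were then at -2.83 (percentile 0.01), the cytotoxic granule genes at -0.54 (percentile 0.155) and the dendritic cell markers at -0.48.

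The levels of the deposited arrays, labelled Ac1-11, were high for T-cell genes, and some genes of other immune cells were present too. On subB, Cd4 lay at percentile 97.7 of all probe sets with a level of 19607, and Thy1 at 99.3, while Cd8a and the B-cell gene Cd79a were called absent on both arrays. Cd74 lay at percentile 95.5 there, H2-Aa at 91.6 and Ighm at 87.6, and on subA Lyz2 lay at 94.3, Spib at 89.9 and Ighm at 88.0. On subA, Cd3e, which like Thy1 is named because its value was seen, lay at percentile 97.8 and Il2ra, the inducible IL-2 receptor chain, at 95.9. The Il2ra probe set of subB, with a level of 284 (percentile 50.5), was called absent on both arrays. Il13 remained among the higher levels of the deposited subA array, at percentile 96.7. The IL-2 probe sets Il2 and IL2_at were called absent on the arrays that carried them. Tnf was called absent on both arrays of each chip, with an approximate fold of 4.8 lower on subA and 3.1 higher on subB. Neither chip had a probe set named Cd69. Of the 406 list genes called present, counted once per chip, 187 lay in the top 10% of a chip's levels, taken over present and absent probe sets alike. As only 45.1% of probe sets on subA and 22.2% on subB were called present, a share above 10% among present genes does not set the lists apart.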

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

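The correlation between chips, its alternatives and all tests in this part were chosen after the values had been seen. The pattern is that 10 genes called as increased or decreased on both chips had opposite directions, all lower on subA and higher on subB, among them the cytokine and chemokine genes Il4, Il10, Csf2, Ccl1 and Ccl4. On the log2 scale, the authors' deposited table gives -7.02 on subA and 2.54 on subB for Ccl1. For Ccl4 it gives -2.83 and 3.29 (-1.38 without a call on subA for the probe set used on subB). Csf2 had -4.63 and 3.43, Il4 -5.32 and an approximate 4.19, and Il10 -1.43 and 1.43. Rgs16 had -2.79 and 2.49, Serpinb9 -2.17 and an approximate 3.41, and Hspa5 -0.93 and 1.26. Gsn had -0.68 and 1.0, and Psmd8 -1.0 and 0.68. The difference between the chips was not tested for any single gene, as each value rests on 1 pair of arrays.

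Noise between probe sets is argued against, because the rank correlation between chips was still -0.319 over the 128 genes left after those called on both were taken out, outside the shuffled range of -0.18 to 0.18. Scaling that depends on the level is argued against as the whole cause, because the rank correlation was -0.389 with the level trend removed, outside the shuffled range of -0.17 to 0.16. Experiment and baseline arrays exchanged on 1 chip would turn genes of every kind, and with the cytokine, chemokine, activation and cytotoxic lists left out the correlation was still -0.356 over 130 genes. Different cultures on the 2 chips, with opposite responses, could give the same -0.356 if they differed throughout, and without replicate arrays this cannot be told apart from an exchange. Neither test says which chip would be turned, so the direction of 4Y against Ac1-11 stays open.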

How the results depend on the processing

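The settings with the level trend removed, approximate folds left out, the sign of subB turned or the highest deposited level, and all settings of the correlation, were chosen after the data were seen. The count of 262 changed probe sets moved most with the difference call: 658 without it, and the share of higher probe sets on subB was then 50.2% instead of 68.1%. It was 112 at a fold threshold of 3, 140 with presence required in both conditions, 149 on subA alone and 113 on subB alone. Other settings gave between 185 and 386. The number of gene lists outside the random range, 8 of 31 with both chips joined, was 3 of 18 on subB alone. Those on subB were the Th2-associated genes, negative regulators and MYC-responsive genes, which are not among the 8. The number was 15 with the sign of subB turned, and between 7 and 11 otherwise. Of the 8, the chemokine list was inside the range without a detection filter (median 0, percentile 41.3), the sterol list with the median over probe sets (-0.50, percentile 3.78) and the ribosomal protein list with the level trend removed (0, percentile 61.3). The interferon-induced list, 0.58 with both chips joined, fell to 0.38 with the level trend removed (percentile 99.7), 0.40 with recomputed folds (percentile 99.8) and 0.38 without a detection filter (percentile 99.7). The cytotoxic granule list went from -0.87 to -0.58 without that filter. Lists that came to lie outside the random range were the Th2-associated genes (0.49, percentile 99.8) and B-cell markers (-0.59, percentile 0.96) with the median over probe sets, and the G2/M genes (-0.24, percentile 2.43) with recomputed folds. B-cell markers (percentile 1.97) and G2/M genes (percentile 1.51) also did so against random lists not matched on level, and G2/M genes with the median over probe sets (percentile 2.41) or the highest deposited level (percentile 2.33). The ribosomal protein list, at 0.38 with both chips joined, was -0.49 on subB alone, and the proteasome list, at -0.26, was 0.14. The correlation of -0.407 between chips stayed below 0 in each setting, from -0.158 without a detection filter to -0.406 with the probe set of the highest deposited level. No paired analysis was possible because each chip had 1 array per condition.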

Other observations

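The tests on spike-in probe sets and on markers of other cell types, and the removal of the level trend, were chosen after the data were seen, and the limits for other cell types were set with the values known. Some changed genes lay outside the T-cell groups described so far. In the authors' deposited table for subA, the T-cell receptor gamma segment Trgv1 was 2.9-fold and 3.3-fold higher by its 2 probe sets, the second over an absent baseline, and was the only gamma-delta T-cell marker detected. The B-cell genes Fcer2a, the low-affinity IgE receptor, and Pou2af1, a transcriptional coactivator, were lower by approximate folds of 8.3 and 4.2 with absent calls on the deposited array, and the list of 7 had a median of -0.68 (percentile 0.97). Among stromal markers, the endothelial cadherin Cdh5 was higher by an approximate 2.4-fold over an absent baseline and Lum, lumican, was 4.1-fold lower with an absent call, with a list median of 0.85, inside the random range (percentile 97.3). Cdc25a, a cell cycle phosphatase, was 2.0-fold lower by 1 of its 2 probe sets.

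On subB, Cd74, the invariant chain of MHC class II, was 2.9-fold higher in the authors' deposited table, the 1 of 2 detected genes of that pathway that counted as changed. Hspa5, a chaperone of the endoplasmic reticulum, was 2.4-fold higher and Psme3, a proteasome activator, was higher by an approximate 2.8-fold. The basophil protease gene Mcpt8 was higher by an approximate 2.9-fold, the 1 of 2 granulocyte markers that counted. The baselines of Psme3 and Mcpt8 were marked absent. Of the CD8 T and NK cell markers only Gzma was detected, and of the erythroid and platelet markers only Hba-a1, at 2.0-fold lower without a difference call. With both chips joined, medians inside the random range were -0.07 for Th1-associated genes, -0.20 for homing receptors, -0.13 for activation markers, -0.07 for resting T cell genes and -0.14 for immediate early genes. They were -0.38 for regulatory T cell markers, -0.20 for the T-cell receptor complex, 0.07 for cytokine receptors, -0.06 for apoptosis-promoting genes and 0.14 for survival genes. For glycolysis, oxidative phosphorylation and chaperone genes the median was 0, for MHC class II genes 0.38, for myeloid markers 0.12 and for housekeeping genes -0.14. Lists given for 1 chip were also inside the joined range: G2/M genes at -0.32, CDK inhibitors and tumour suppressors at 0, MYC-responsive genes at -0.14, B-cell markers at -0.47 and stromal markers at 0. With the sign of subB turned, 5 of the lists in these sentences lay outside: homing receptors at 0.38 (percentile 97.8), CDK inhibitors and tumour suppressors at 0.58 (percentile 99.9), MYC-responsive genes at -0.26, B-cell markers at -0.53 (percentile 1.41) and stromal markers at 0.85 (percentile 98.8).

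Abundant transcripts, those of ribosomal proteins among them, were higher on the deposited subA array. The bacterial spike-in probe sets, which do not come from the cells, had a median log2 fold of 0.68, so scaling between the arrays could account for this. Whether the rise of the spike-in probe sets depended on their level was not tested. The ribosomal protein list's median went from 0.43 to 0.11 with the level trend removed, at percentile 93.1 of random lists, inside their range. A rise of these transcripts beyond others of their level stays open, as 0.107 lies close to the limit of 0.1 set for excluding it.

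Interferon-induced genes were higher on the deposited subA array although Ifng was lower, and no biological explanation was tested. Scaling by level is argued against as the whole cause, because the list's median was 0.563 with the trend removed, at percentile 100, although with both chips joined it fell from 0.58 to 0.38. A larger share of B cells and dendritic cells in the RNA would have to lift their markers about as far as the list's 0.63. Of 6 such markers present on both subA arrays 0 were higher, with a median of -0.20 and an SD of 0.36. Activated T cells can also express 2 of them, Batf3 and Cd86. The signal of Ighm and Spib may not come from B cells, as Cd79a was called absent on both subB arrays. As the source of most of these markers is uncertain, they cannot decide about B cells and dendritic cells, and they do not cover other cell types. A larger share of myeloid cells, which purification for CD4 would remove, could contribute and stays open, with a list median of 0.38 (percentile 93.6) and no difference call in the list. Lyz2 (level 5294, implied baseline level 2286, 7 of 20 probe pairs increased), Fcgr3, C1qb, Ctsb (level 11814) and Ctss were higher, by a deposited 6.2-fold that exceeds the ratio of these levels, by an approximate 3.1-fold and by 1.3-fold for each of the last 3, and Cd68 and Fcer1g were 1.1-fold and 1.7-fold lower.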
